A study of Mus musculus with 241 samples.

How the data were processed

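Gene expression was measured in 12 bulk RNA libraries of 5 sorted populations, in 2 droplet single-cell libraries (10x) and in 227 cells captured on the C1 chip. Per the labels, some bulk libraries were made with NEBNext Ultra and others from amplified cDNA with SMART-Seq v4, and this kit differs within every bulk population except total ETP. Per the submitters' processing notes, the bulk reads were aligned with STAR 2.4.0 and RSEM 1.2.25 to mm10. The deposited bulk values are FPKM, which the authors computed with HOMER as reads on the exons of each RefSeq gene model per kilobase of the model, scaled to the library size. The C1 values are FPKM deposited by the authors from RSEM, with 43346 genes. The 10x matrices hold UMI counts that the authors made with Cell Ranger 2.0. edgeR 3.6.8 is also named in the notes.

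Since the bulk values are FPKM and not counts, the test was limma 3.58.1 in R 4.3.3 with a trend of the variance, on log2(FPKM + 1). All 12 libraries entered a single fit with the population and the kit as terms. Of 24506 genes, 12112 with more than 1 FPKM in at least 2 libraries were tested, a filter chosen after the unit was known. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With a pseudocount of 1, folds understate changes in genes at low FPKM. The 4 comparisons were Flt3- against Flt3+ ETP, Bcl11b- DN2a against Flt3- ETP, Bcl11b+ against Bcl11b- DN2a, and Bcl11b- DN2a against total ETP. The comparisons, tests, gene lists, gene pairs and most alternatives were chosen before the data were examined.

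Genes were named by a rule: the 10 largest rises and the 10 largest falls (5 of each for total ETP) among called genes with a mean log2 value of at least 3 and the same sign in every library-number series, besides regulators and gate genes listed beforehand and up to 4 examples per list by smallest adjusted p. Predicted genes without a name were left out of the text. Lists of genes for progenitor and T-lineage functions, cell division, responses and other cell types were tested with camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists of a comparison. Coordinates are 1-based spans of the gene models on mm10.

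Whole read numbers were recovered from FPKM and the listed gene lengths. Within a tolerance of 0.1 read, 91.3% to 98.7% of values came out whole, against at most 21.4% with a wrong step. Between libraries of a population, Spearman correlations across genes were 0.965 to 0.99 within a kit and 0.809 to 0.844 between kits. Chi-square per degree of freedom between such libraries, on recovered reads, was 14.6 for total ETP and 60.5 to 1160.7 for the others, so the spread between libraries exceeds counting error. On simulated data, the fit recovered 65% to 81.1% of changes of 1 on the log2 scale and 97.3% to 99.2% of changes of 2. Each of 10 draws changed 100 genes per fold size, and a mean of 4.24% to 6.11% of calls were false. The simulated noise was independent between libraries and genes. Real deviations of libraries, with population and kit removed, correlated by up to 0.823, so these rates need not hold for the real data.

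The 10x cells were kept with at least 1000 genes and under 10% mitochondrial UMIs, which removed 27 and 427 cells for genes and 102 and 23 for mitochondrial UMIs. Scrublet called 1 and 3 doublets, or 0.02% and 0.0338% of barcodes, and so has not worked as a doublet filter. Kept cells had median depths of 8488 and 6136 UMIs and 2348 and 1977 genes. Counts were log-normalized and centred within each library, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 were used (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, seed 1). Clusters were named where the mean log2 fold of a class's markers against other cells was at least 0.5, with at least 3 markers each in at least 5% of cells, and no other class had more markers among the 10 leading genes than the class itself. These numbers, and the thinning depth of 4000 UMIs, were chosen after the deposited values were seen and before the clusters were. The pipeline put 100% of 1500 simulated cells from 3 populations in the cluster of their own population, at a fold of 4 in 200 genes. These populations were discrete and their cells varied only by depth and random sampling of UMIs. The result therefore does not show how well neighbouring states are separated in the real cells.

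Detection in C1 cells meant more than 1 FPKM, in the 222 of 227 cells with at least 1000 such genes. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals and odds ratios carry 95% counting intervals. Computation used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. The alternatives were quantile normalization, a pseudocount of 0.1, no filter, no kit term, NEBNext libraries only, blocks for the replicate number or the library-number series, the compared populations only, and each library left out. For single cells they were other cell filters, resolutions, thinning depths and detection thresholds. Tests on recovered reads with edgeR 4.0.16 and DESeq2 1.42.0 were added after the data were seen.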

Results

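Early T-cell development was profiled in mouse thymus by sequencing RNA from sorted populations (bulk) and from single cells. All cells were lineage-negative and carried surface CD44 and Kit. Within this gate, early T-cell progenitors (ETPs), the earliest thymic precursors, lack CD25, and DN2a cells, the following stage, carry it. The bulk samples came from mice whose Bcl11b gene carries a yellow fluorescent reporter. Bcl11b encodes a transcription factor that comes on at T-lineage commitment. ETPs were sorted as Flt3+ (2 libraries), Flt3- (2 libraries) or undivided, called total ETP (2 libraries), and DN2a cells as reporter-negative (Bcl11b- DN2a, 3 libraries) or reporter-positive (Bcl11b+ DN2a, 3 libraries). Single cells of wild-type mice from the whole gate were profiled with 10x droplets (2 libraries) and with a microfluidic chip, the C1. The 12 bulk libraries held 21206645 to 38537039 reads on gene models, recovered from the deposited FPKM values. The 10x libraries held 43734920 UMIs (unique molecular identifiers, which count RNA molecules) over 5006 barcodes and 55522900 over 8867 barcodes. Nothing in the labels ties replicate libraries to separate mice, so p-values measure the spread between these libraries, which may be technical.

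The gate genes were measured first, as a check of the sorts. Flt3 stood at 78.5 and 61.9 FPKM in the Flt3+ ETP libraries and at 19.3 and 24.9 FPKM in the Flt3- ETP libraries. Il2ra, which encodes CD25, lay between 1.02 and 18.4 FPKM in the 6 ETP libraries and between 183.6 and 300.8 FPKM in the 6 DN2a libraries. Bcl11b lay between 0.596 and 6.11 FPKM in Bcl11b- DN2a and between 16.1 and 44.3 FPKM in Bcl11b+ DN2a. In 2 ETP libraries, replicate 1 of Flt3+ and of Flt3-, Bcl11b was at 5.76 and 4.54 FPKM, against 0.167 FPKM or less in the other ETP libraries.

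Flt3- ETPs were compared with Flt3+ ETPs to ask how progenitors on either side of the Flt3 gate differ. Transcripts for proteins stored in granulocyte and mast cell granules were higher in the Flt3- cells. Prtn3, which encodes the neutrophil protease proteinase 3 (chromosome 10, 79879667 to 79883172, plus strand, mm10), rose by 4.15 ± 0.33 on the log2(FPKM + 1) scale (SE, 2 libraries against 2, adjusted p = 0.000124). It measured 165.1 and 167.3 FPKM in the Flt3- libraries and 11.4 and 6.09 FPKM in the Flt3+ libraries. Other rises were Ctsg, encoding cathepsin G (3.05 ± 0.38), Mpo, encoding myeloperoxidase (1.69 ± 0.25), Cpa3, encoding a mast cell carboxypeptidase (2.67 ± 0.21), and the Fc receptor subunit gene Fcer1g (1.35 ± 0.18). Cd160 (1.75 ± 0.20), Lst1 (1.56 ± 0.21), Rab44 (1.36 ± 0.23), Muc13 (1.28 ± 0.21) and Olfm5 (1.24 ± 0.17) completed the 10 largest rises among called genes with a mean log2 value of at least 3. Tcf7, encoding the T-cell factor TCF1 (chromosome 11, 52252283 to 52282595, minus strand), rose by 0.96 ± 0.12 (adjusted p = 0.00364), and Gfi1b, encoding a transcriptional repressor of erythroid and megakaryocytic cells, by 1.18 ± 0.22 (adjusted p = 0.0402).

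Of the 18 measured genes of the myeloid and granulocyte list, 9 rose and none fell, and 13 rose when adjusted over the list alone (camera adjusted p = 2.4e-22, and adjusted p = 0.0101 with an estimated correlation). Elane, encoding neutrophil elastase, rose by 6.20 ± 0.40, S100a8 by 4.13 ± 0.38 and Fcgr3 by 2.63 ± 0.24. In the erythroid, megakaryocyte and mast cell list, 3 of 11 rose, namely Cpa3, Mcpt8 (2.64 ± 0.31) and Ms4a2 (1.38 ± 0.22), and 8 rose when adjusted over the list alone (adjusted p = 2.04e-17, and adjusted p = 0.00178 with an estimated correlation). Both lists were fixed as markers of other cell types that the gate could hold. In the 10x libraries, 98.9% and 97.9% of Elane UMIs and 85.9% and 87.1% of Prtn3 UMIs lay in a small cluster of myeloid-like cells, which held 19.3% and 10.6% of Mpo UMIs and 2.11% and 1.57% of Cpa3 UMIs.

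Several genes of mitosis were among the falls in Flt3- ETPs. Besides Flt3, the gate gene, the largest falls among called genes with a mean log2 value of at least 3 were in Prc1 (-1.09 ± 0.20), Nek2 (-0.98 ± 0.19), Pygb (-0.98 ± 0.19), Bub1b (-0.97 ± 0.17), Kif4 (-0.95 ± 0.19), Tpx2 (-0.92 ± 0.17), Kif20a (-0.89 ± 0.14), Kif2c (-0.88 ± 0.17) and Racgap1 (-0.87 ± 0.15), all of which except Pygb act in mitosis. None of these falls kept its call without Flt3- ETP replicate 1. Of the 24 G2/M genes, 3 fell and 19 fell when adjusted over the list alone (adjusted p = 9.73e-12, but adjusted p = 0.0993 with an estimated correlation). None of 24 S-phase genes passed over all genes and 16 fell when adjusted over the list alone (adjusted p = 1.41e-05, but adjusted p = 0.274 with an estimated correlation). The chemokine receptor gene Ccr9 fell by 1.96 ± 0.25 (adjusted p = 0.00364). Of the 16 interferon-stimulated genes only Irf7 fell (-0.83 ± 0.16), and the list's call was lost with an estimated correlation (adjusted p = 0.254). Progenitor regulators had 1 rise in 18, Gfi1b, and T-lineage regulators 1 in 17, Tcf7. The call of the progenitor surface list, whose 1 fall in 12 was Flt3, the gate gene, was lost with an estimated correlation (adjusted p = 0.363). So was the call of the natural killer and innate lymphoid list, with 1 rise in 12 (adjusted p = 0.116). None of 18 genes of the T-cell receptor complex and recombination passed. In replicate 1 of Flt3+ and of Flt3- ETP, the libraries of the first library-number series, Cd3g averaged 46.2 FPKM and Cd3e 13.7 FPKM, against 0.998 and 0.383 FPKM in total ETP and 3.07 and 0.851 FPKM in replicate 2. Spi1 (0.24 ± 0.25), Lmo2 (-0.50 ± 0.28), Bcl11a (-0.46 ± 0.17) and Mef2c (-0.77 ± 0.28) did not pass.

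In all, 83 of 12112 genes passed in this comparison, 51 higher and 32 lower in Flt3- ETPs, against a median change over all genes of -0.15. The library numbers form 3 series, and with these as the block 588 genes passed, 36.9% of them higher. Each of the 83 calls had the same sign in both series that hold both populations, with 1 library per population in each. The calls were made on these same libraries, so the shared sign was largely fixed by the selection. The split was 50 higher and 5 lower after quantile normalization, 43 and 8 with a pseudocount of 0.1, and 66 and 31 after median-ratio scaling. The count was 24 or 14 without Flt3+ replicate 1 or 2, 30 without Flt3- replicate 1, all of them rises, and 1605 without Flt3- replicate 2, with only 20.6% of them higher. The balance of rises and falls therefore depends on the libraries used. Of the named genes, 17 lost their call and 5 kept it without Flt3+ replicate 1, and 19 lost it and 3 kept it without Flt3+ replicate 2, Mpo and Tcf7 being among those lost both times. Over this and the next comparison, 24 lost their call and 25 kept it without Flt3- replicate 1, and 1 lost it without Flt3- replicate 2.

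**Figure D1:**
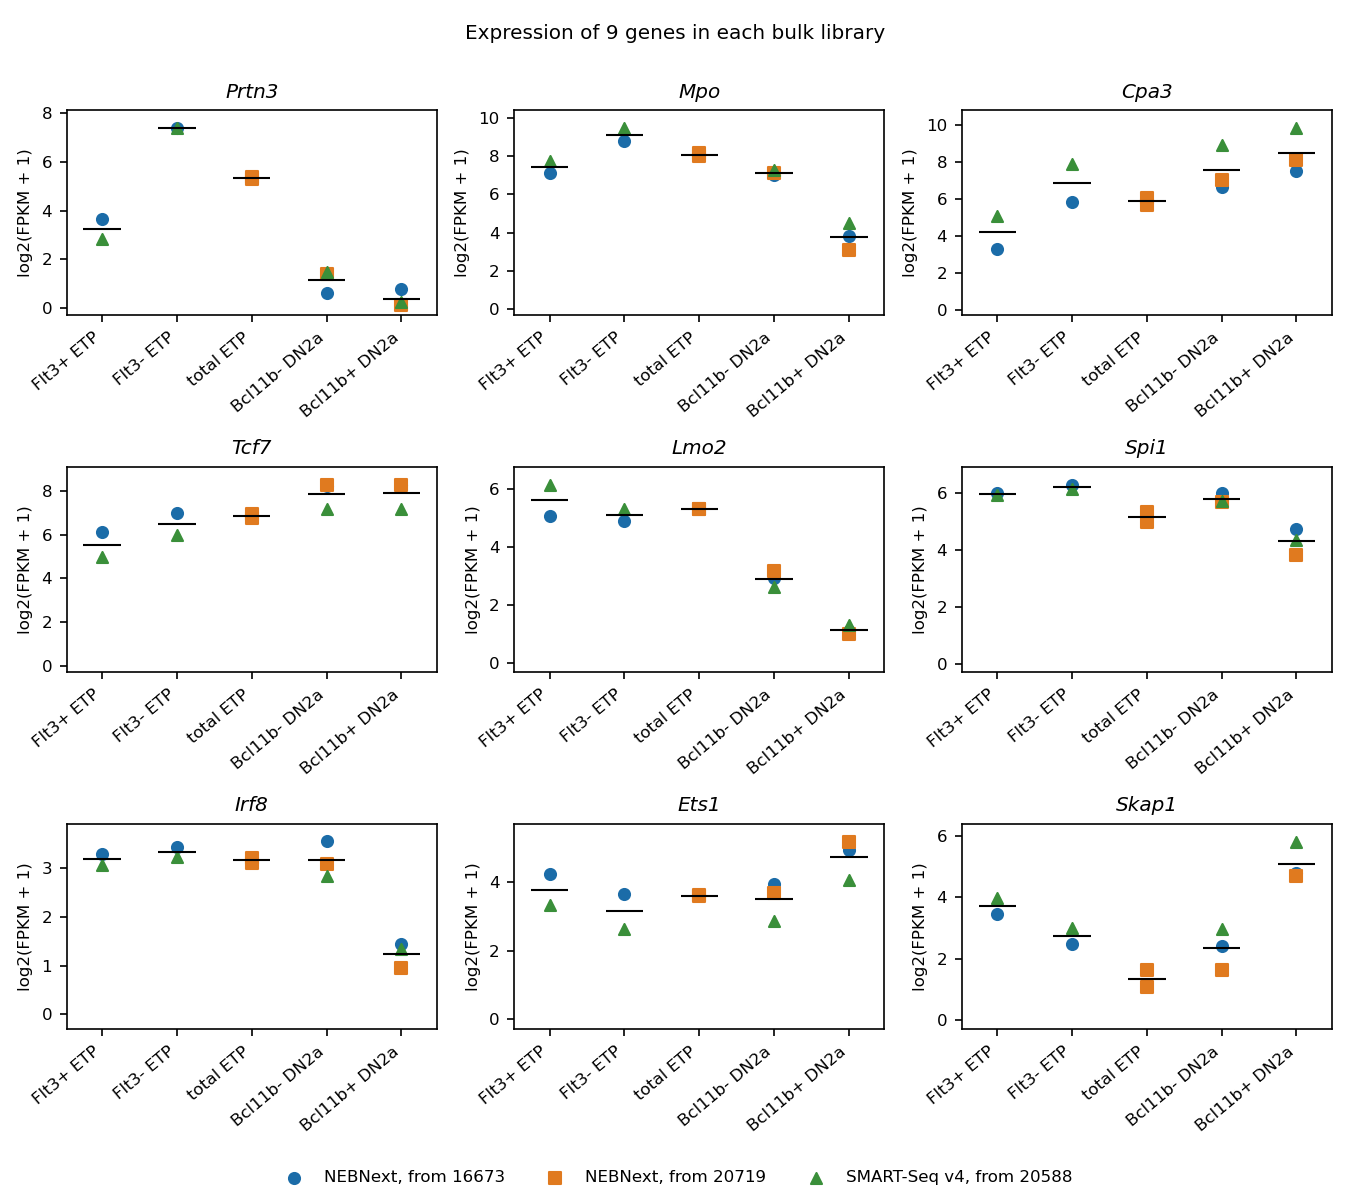
Expression of 9 genes in the 12 bulk libraries, as log2(FPKM + 1) on the vertical axis and the 5 sorted populations on the horizontal axis. Each point is a library, marked by its library preparation kit and library-number series, and the bar is the mean of the population. Prtn3 was at 165.1 and 167.3 FPKM in Flt3- ETP and at 1.81 FPKM or less in the DN2a libraries.

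Bcl11b- DN2a cells were compared with Flt3- ETPs to follow the entry into the CD25+ stage. Besides Il2ra, the gate gene, the largest rise was in Fgf3, encoding a fibroblast growth factor (chromosome 7, 144838612 to 144843348, plus strand), at 4.05 ± 0.25 (SE, 3 libraries against 2, adjusted p = 6.15e-06). It measured 3.39 and 1.75 FPKM in Flt3- ETPs and 47.8 to 75.2 FPKM in Bcl11b- DN2a. Il7r, encoding the interleukin-7 receptor, rose by 2.11 ± 0.21 (adjusted p = 0.000324). Among called genes with a mean log2 value of at least 3, the next rises were Scin (1.75 ± 0.15), Il12rb2 (1.74 ± 0.27), the integrin gene Itga4 (1.71 ± 0.32), Aldh1b1 (1.62 ± 0.25), Dpp4 (1.62 ± 0.20), Fut8 (1.61 ± 0.17) and Muc13 (1.57 ± 0.19). Among the same genes the largest fall was in Prtn3 (-6.24 ± 0.30, adjusted p = 1.46e-06), with falls in Flt3 (-3.28 ± 0.28), the cathepsin genes Ctss (-2.88 ± 0.31) and Ctsg (-2.75 ± 0.35), Anxa1 (-2.49 ± 0.14), Il12a (-2.45 ± 0.29), S100a4 (-2.13 ± 0.35), Evl (-2.06 ± 0.21) and Egfl7 (-1.93 ± 0.24). Lmo2, encoding a transcriptional adaptor of blood progenitors (chromosome 2, 103970287 to 103981878, plus strand), fell by 2.15 ± 0.25 (adjusted p = 0.000896).

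Of the 18 progenitor regulators, 4 fell, which were Lmo2, Hoxa9 (-1.28 ± 0.18), Meis1 (-1.09 ± 0.23) and Cebpa (-2.0 ± 0.29), and none rose, while Spi1 (-0.41 ± 0.23) and Bcl11a (-0.05 ± 0.15) did not pass. The camera call of this list was lost with an estimated correlation (adjusted p = 0.325). Of the 17 T-lineage regulators 4 rose, Tcf7 (1.21 ± 0.11, adjusted p = 0.000186), Gata3 (0.98 ± 0.22), Tcf12 (0.83 ± 0.18) and Runx1 (0.85 ± 0.21), and 7 rose when adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). In the myeloid and granulocyte list 12 genes fell and 1 rose, with 13 falls when adjusted over the list alone (adjusted p = 7.77e-18, and adjusted p = 0.0364 with an estimated correlation). Its examples were Elane (-7.81 ± 0.36), S100a8 (-4.59 ± 0.35) and S100a9 (-2.88 ± 0.32). In the droplet libraries, 67.4% and 75.8% of Cebpa UMIs lay in the small cluster of myeloid-like cells. The same cluster held 98.9% and 97.9% of Elane UMIs and 62.5% and 45% of Ctsg UMIs. The falls in Cebpa and in the myeloid genes may therefore reflect such cells in the ETP libraries, rather than a change within ETPs. This was not tested for this comparison. Of 24 S-phase genes 6 rose and 19 rose when adjusted over the list alone, among them Cdc6 (0.75 ± 0.16) and Rrm2 (0.72 ± 0.15), with adjusted p = 0.0997 with an estimated correlation. Of 12 progenitor surface genes 5 fell, including Cd34 (-1.27 ± 0.18) and Csf1r (-1.84 ± 0.27), and of 16 interferon-stimulated genes 4 fell, including Irf7 (-0.83 ± 0.15). The calls of both lists were also lost with an estimated correlation (adjusted p = 0.0997 for each).

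In total 481 genes passed, 40.7% of them higher in Bcl11b- DN2a. With the library-number series as the block 937 passed, 48.3% of them higher. Each of the 481 calls had the same sign in both series that hold both populations, which was largely fixed by calling them on these libraries. The 481 genes are 1.96% of the 24506 genes in the table, and this share was 0.673% without Flt3- ETP replicate 1, 10.4% without Flt3- ETP replicate 2, 1.1% without Bcl11b- DN2a replicate 1 and 1.12% without Bcl11b- DN2a replicate 3. The direction of the balance was not stable: 73.4% of the called genes were higher with NEBNext libraries only and 76.5% without Flt3- ETP replicate 2, but 15.2% without Flt3- ETP replicate 1.

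Bcl11b+ DN2a cells were compared with Bcl11b- DN2a cells to ask what accompanies the activation of the reporter. Genes of T-cell receptor signalling were higher in the reporter-positive cells and regulators of uncommitted progenitors were lower. Skap1, encoding an adaptor protein of T-cell receptor signalling (chromosome 11, 96464591 to 96759622, plus strand), rose by 2.76 ± 0.22 (SE, 3 libraries against 3, adjusted p = 8.66e-05), from 2.10 to 6.81 FPKM up to 25.1 to 55.4 FPKM. Thy1 (2.14 ± 0.33), Fam169b (2.09 ± 0.33), Lgals1 (1.81 ± 0.26), Rgcc (1.79 ± 0.26), Nck2 (1.73 ± 0.13), Trat1 (1.63 ± 0.33), Anxa2 (1.34 ± 0.26), Cd247, encoding the T-cell receptor zeta chain (1.24 ± 0.19), and the transcription factor gene Ets1 (1.22 ± 0.13, adjusted p = 0.000463) also rose. Among called genes with a mean log2 value of at least 3, Mpo fell most, by 3.34 ± 0.20 (adjusted p = 1.82e-05). It went from 127.2 FPKM or more in Bcl11b- DN2a to 21.8 FPKM or less in Bcl11b+ DN2a. Further falls were in Serpina3g (-2.46 ± 0.16), Spns2 (-2.24 ± 0.14), the signalling adaptor gene Tyrobp (-2.02 ± 0.22), Cd7 (-1.93 ± 0.18), Slc35d3 (-1.92 ± 0.13), Ctsg (-1.84 ± 0.31), Car2 (-1.82 ± 0.17), Cd33 (-1.78 ± 0.16) and Lmo2 (-1.76 ± 0.23).

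Among the 18 progenitor regulators, 10 fell and none rose, and 11 fell when adjusted over the list alone (adjusted p = 1.38e-15, and adjusted p = 0.0313 with an estimated correlation). Spi1, encoding the myeloid and lymphoid regulator PU.1 (chromosome 2, 91096678 to 91115759, plus strand), fell by 1.5 ± 0.20 (adjusted p = 0.00237). The other falls were in Irf8 (-1.91 ± 0.19), Gfi1b (-1.48 ± 0.18), Mef2c (-1.19 ± 0.23), Bcl11a (-1.12 ± 0.14), Hhex (-1.01 ± 0.19), Lmo2, Meis1 (-0.93 ± 0.20), Hoxa9 (-0.85 ± 0.16) and Mycn (-0.69 ± 0.16). Of the 17 T-lineage regulators 4 rose, Bcl11b (the gate gene), Ets1, Tcf12 (0.85 ± 0.16) and Gfi1 (0.65 ± 0.15), whereas Tcf7 (0.02 ± 0.10) and Gata3 (0.37 ± 0.19) did not pass. The camera test of this list gave adjusted p = 0.0323 with an estimated correlation. It included Bcl11b, so part of the list's rise was fixed by the sort, and the list was not tested without this gene. Of the 18 genes of the T-cell receptor complex and recombination 7 rose and 12 rose when adjusted over the list alone (adjusted p = 2.58e-16, and adjusted p = 0.0313 with an estimated correlation), such as Rag2 (0.93 ± 0.15). Of the 24 G2/M genes 6 rose, 19 when adjusted over the list alone, and of the 24 S-phase genes 4 rose, 11 when adjusted over the list alone, with adjusted p = 0.0313 and 0.0323 with an estimated correlation. Birc5 rose by 0.73 ± 0.12 and Rrm2 by 0.81 ± 0.13. In the myeloid and granulocyte list 5 of 18 fell (adjusted p = 0.0323 with an estimated correlation), among them Fcgr3 (-1.78 ± 0.20).

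In total 338 genes passed, 41.1% of them higher in Bcl11b+ DN2a. With the library-number series as the block 682 passed, 45.7% of them higher. Each of the 338 calls had the same sign in all 3 series, which was largely fixed by calling them on these libraries. The 338 genes are 1.38% of the 24506 genes in the table, and this share was 0.649%, 0.792% or 0.8% without Bcl11b- DN2a replicate 1, 2 or 3, and 0.763% without Bcl11b+ DN2a replicate 3.

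Bcl11b- DN2a cells were also compared with total ETPs. Fgf3 rose by 4.73 ± 0.26 and Il2ra, the gate gene, by 4.92 ± 0.51, while Flt3 (-4.44 ± 0.28), Prtn3 (-4.16 ± 0.31), the adhesion receptor gene Adgrl4 (-2.93 ± 0.32), Ctss (-2.73 ± 0.31) and Il12a (-2.61 ± 0.30) fell. The beta-globin genes Hbb-b1 (3.5 ± 0.46), Hbb-bs (3.5 ± 0.46) and Hbb-b2 (3.48 ± 0.45) also passed, but their near-identical sequences share reads and the values of each are uncertain. Of the 18 progenitor regulators 7 fell and 4 rose. Of the 11 Notch response genes 5 rose, namely Il2ra, the gate gene, Gata3, Tcf7 (1.39 ± 0.11), Notch3 (2.04 ± 0.32) and Dtx1 (1.70 ± 0.33). The list had a camera adjusted p = 6.7e-05, but adjusted p = 0.0686 with an estimated correlation. Since the list includes Il2ra, part of its rise was fixed by the sort. Notch3 was uneven, at 8.11, 3.10 and 0.197 FPKM in Bcl11b- DN2a replicates 1, 2 and 3. In replicate 1 of Flt3+ and of Flt3- ETP, Notch3 was at 6.76 and 4.44 FPKM and Dtx1 at 3.93 and 5.88 FPKM. In total 1895 genes passed, 1184 higher and 711 lower. Total ETP libraries came from a single library-number series, and with the series as the block 940 genes passed, 58.4% of them higher. The 1895 genes are 7.73% of the 24506 genes in the table, and this share was 1.62% or 0.828% without total ETP replicate 1 or 2, and 1.53%, 11.8% or 3.28% without Bcl11b- DN2a replicate 1, 2 or 3. The balance was not stable, with 62.5% of the called genes higher in this fit, 51.3% after quantile normalization, 48.4% without Bcl11b- DN2a replicate 1, 42.9% with NEBNext libraries only and 39.4% without total ETP replicate 2.

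The 10x cells were clustered to ask which states the gate holds. After filtering, 4877 and 8431 cells formed 14 clusters. ETP-like cells, named by their score on progenitor markers, made up 17.4% (95% exact binomial interval 16.3% to 18.5%) and 14.9% (14.2% to 15.7%) of the libraries, 16.2% ± 1.71 (SD, n = 2). Their 2 clusters, 4 and 7, scored 0.51 and 0.501 against a naming threshold of 0.5. Flt3 and Hoxa9 were among the leading genes of cluster 4, whereas cluster 7 was led by division genes such as Ube2c, Top2a and Mki67, with 0 progenitor markers among its 10 leading genes, and the share ranged from 9.09% to 19.3% across settings. Committed-like cells in clusters 8, 11 and 13, led by Cd3 genes, Ptcra or Lef1 (with Gzma also leading in cluster 11), made up 10.0% ± 1.08 (SD, n = 2). Cluster 13, with 10 and 50 cells, had a median doublet score of 0.338, against 0.0162 to 0.0923 in the other clusters. Myeloid-like cells in cluster 12, led by Prtn3, Elane, Ctsg and Ms4a3, with Gzmb and Pf4 of other classes also among the leading genes, numbered 45 and 48, which is 0.746% ± 0.25 (SD, n = 2). The remaining 73.1% ± 0.886 (SD, n = 2) stayed unnamed, since their highest class score was under 0.5 or, in cluster 0, Klrd1 of another class but no progenitor marker was among the leading genes. Cluster 0 held 21.1% and 19.5% of the libraries, with an ETP score of 0.72, above those of clusters 4 and 7. The ETP-like share therefore depends strongly on the rule about leading genes. Cluster 1, led by Bcl11b and Il7r, had a DN2 score of 0.48, and a DN2-like class was named only when the called doublets were kept. The naming thresholds were set after the deposited values had been seen and before the clusters were. Intervals cover counting error only.

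Each cluster was set beside the bulk populations by the Spearman correlation of centred expression across 725 genes called in the first 3 comparisons. These correlations are across genes, which are not independent replicates, and these genes were chosen for differing between the populations. Over all 6779 expressed genes most values were lower, and they follow in brackets where they fell by over 1.5 times in at least 1 library. The ETP-like clusters 4 and 7 lay nearest to Flt3+ ETP, with correlations of 0.718 and 0.746 for cluster 4 in libraries 1 and 2 (0.245 and 0.276) and of 0.666 and 0.683 for cluster 7 (0.347 and 0.336). Cluster 0, led by Cd7, Evl and Klrd1, lay nearest to Flt3- ETP at 0.678 and 0.704 (0.395 in each). Clusters 2 and 3, where Hbb-bt and Fgf3 were among the leading genes, lay nearest to Bcl11b- DN2a, at 0.647 and 0.68 (0.31 and 0.304) and at 0.605 and 0.622 (0.232 and 0.24). Clusters 1 and 6 lay nearest to Bcl11b+ DN2a, at 0.773 and 0.793 (0.501 and 0.534) and at 0.778 and 0.732, cluster 6 being led by histone and mitosis genes such as Top2a and Mki67. The myeloid-like cluster reached 0.282 and 0.333 with Flt3- ETP (0.089 and 0.164). Of the 14 clusters, 12 had the same nearest population in both libraries.

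**Figure D2:**
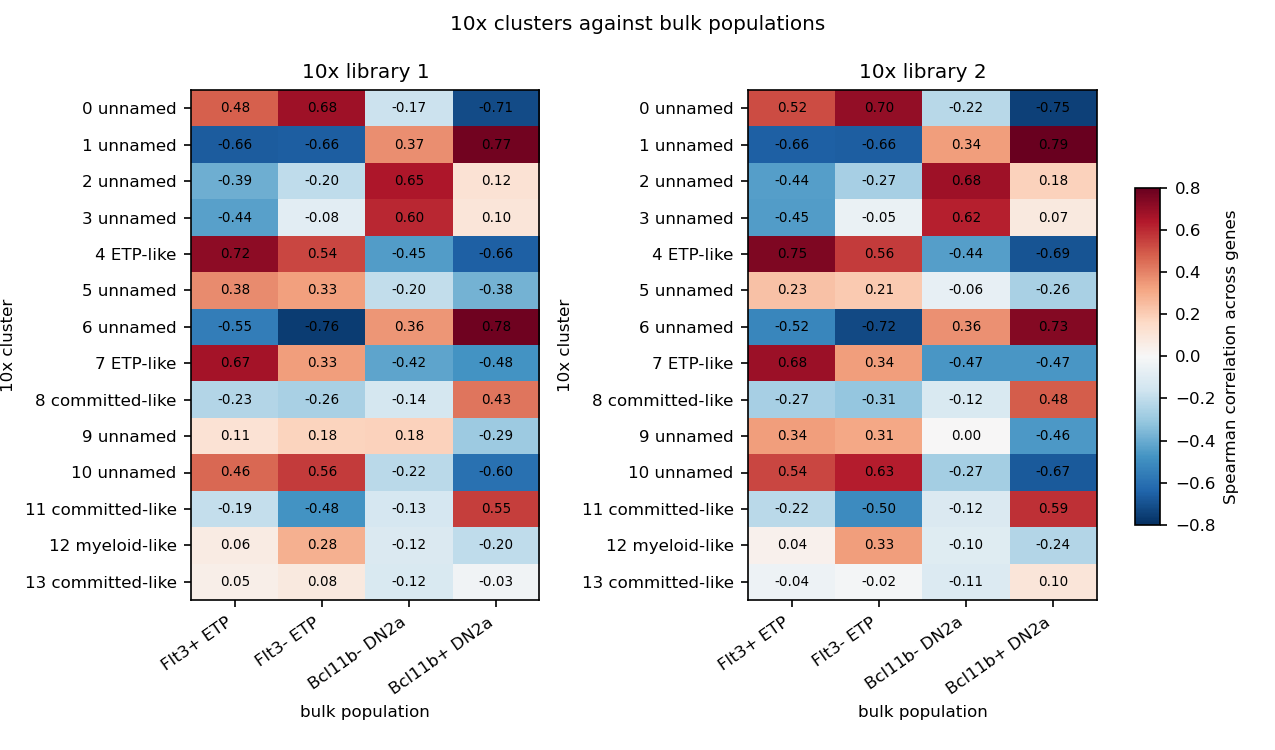
Spearman correlation across 725 genes between each of the 14 clusters (vertical axis) and each of 4 bulk populations (horizontal axis), with 1 panel per 10x library and the colour and the printed value giving the correlation. Cluster 4 reached 0.718 and 0.746 with Flt3+ ETP, and cluster 1 reached 0.773 and 0.793 with Bcl11b+ DN2a, against 0.245 and 0.276, and 0.501 and 0.534, over all 6779 expressed genes.

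Pairs of genes were then examined for detection in the same cell, to ask whether regulators of progenitors and of T cells are found together. Cells were thinned to 4000 UMIs, which left 4627 and 6975 cells and left out 250 and 1456 shallower ones. The committed-like cluster 8 had median depths of 3848 and 3206 UMIs, so that many of its cells were left out. Flt3 and Il2ra were detected together less often than independent detection would give, with odds ratios of 0.0593 (95% interval 0.0323 to 0.109) and 0.101 (0.0683 to 0.15). Without thinning the ratios were 0.0973 and 0.126. Lmo2 with Bcl11b gave 0.0783 (0.0481 to 0.127) and 0.122 (0.0893 to 0.166), and without thinning 0.0865 and 0.107. Thinning to 2000 UMIs gave 0.054 and 0.0685 for this pair. Mef2c with Bcl11b gave 0.131 and 0.185 (0.13 and 0.175 without thinning), and Spi1 with Bcl11b gave 0.315 and 0.355 (0.287 and 0.284 without thinning). Il2ra (5.75 and 5.59, and 11.2 and 7.33 without thinning), Tcf7 (2.23 and 2.82, and 2.93 and 2.84) and Gata3 (1.97 and 2.08, and 2.23 and 2.38) were detected with Bcl11b more often than independent detection would give. Of 16 pairs fixed beforehand, 11 lay below 1 and 5 above 1 in both libraries, against 10 and 5 with 2000 UMIs.

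**Figure D3:**
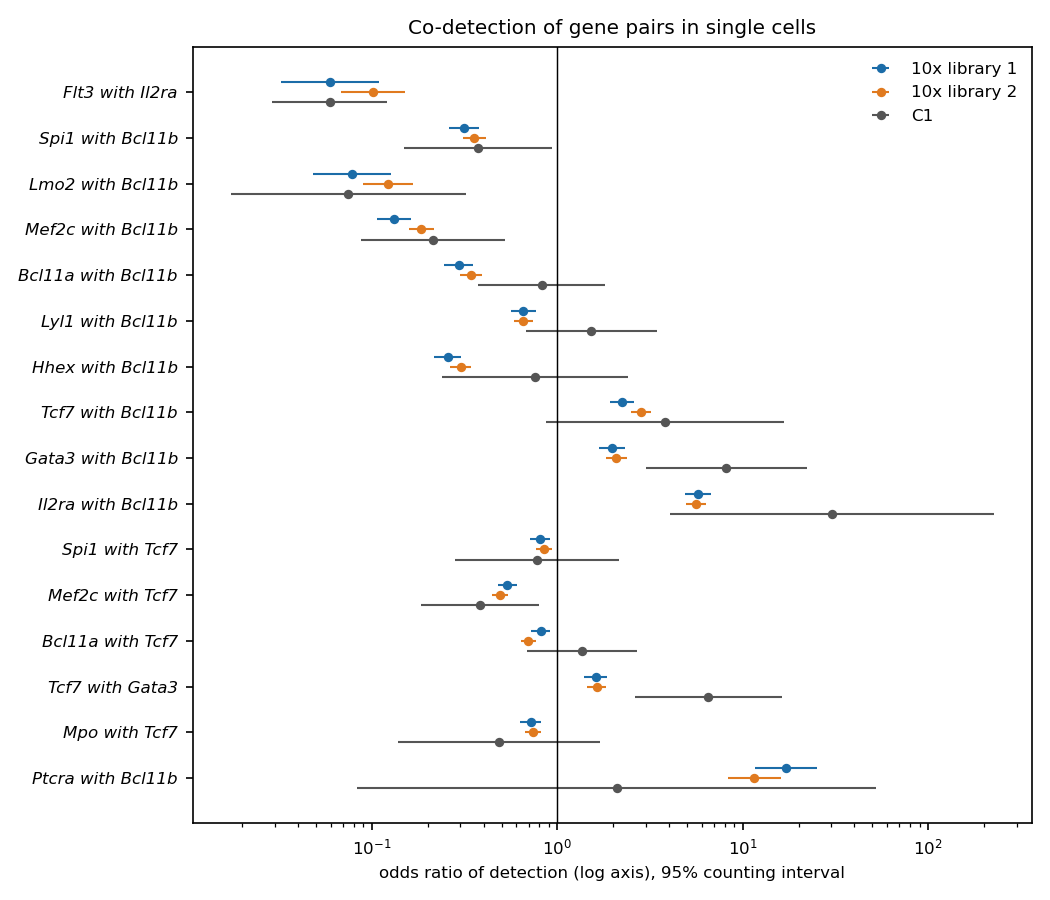
Odds ratios of detection in the same cell for 16 gene pairs (vertical axis) on a log axis, with points for the 2 10x libraries thinned to 4000 UMIs per cell and for the C1 cells, and lines for 95% counting intervals. Flt3 with Il2ra lay at 0.0593, 0.101 and 0.0591, and Il2ra with Bcl11b at 5.75, 5.59 and 30.2, and with C1 detection above 0 FPKM the last values were 0.155 and 8.93.

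The C1 cells gave full-length transcript values for the same gate. Cells with at least 1000 genes above 1 FPKM were kept. Regulators of progenitors were detected above 1 FPKM in many cells, with Nfe2 in 91.4% (87% to 94.8%), Hhex in 89.2% (84.3% to 92.9%) and Spi1 in 86% (80.8% to 90.3%), while Lmo2 was detected in 43.2% (36.6% to 50%). Among T-lineage regulators, Myb was detected in 93.2% (89.1% to 96.2%), Runx1 in 81.5% (75.8% to 86.4%), Tcf7 in 80.6% (74.8% to 85.6%), Gata3 in 44.1% (37.5% to 50.9%) and Bcl11b in 13.5% (9.31% to 18.7%). Mpo was detected in 87.8% and Elane in 6.76% of cells. For some genes, common ones included, detection depended on the threshold. Lyl1 was detected in 58.1% of cells above 1 FPKM, 73.4% above 0 FPKM and 26.6% above 5 FPKM. Elane was detected in 11.3% above 0 FPKM and 3.6% above 5 FPKM, and Bcl11b in 17.1% and 7.21%. Detection also differed between the 4 library-number series, with Elane in 1.09%, 26.1%, 0% and 8.42% of their cells. Bcl11b was detected in 16.3%, 21.7%, 0% and 10.5% of the cells of the series. Of the 40 regulators measured, 16 were detected in over 50.0% of the cells, against 19 with detection above 0 FPKM and 12 above 5 FPKM. The odds ratio was 0.0591 (0.029 to 0.12) for Flt3 with Il2ra, 0.0745 (0.0173 to 0.321) for Lmo2 with Bcl11b (0.155 and 0.168 with detection above 0 FPKM) and 0.374 (0.149 to 0.938) for Spi1 with Bcl11b, where detection above 0 FPKM gave 0.432 with an interval that includes 1 (0.173 to 1.08). It was 8.15 (2.99 to 22.2) for Gata3 with Bcl11b (4.56 above 0 FPKM), and for Tcf7 with Bcl11b it was 3.8 with an interval that includes 1 (0.869 to 16.6). Some pairs that lay below 1 in both 10x libraries were not below 1 here beyond counting error. Among them, Lyl1 with Bcl11b gave 1.52 (0.677 to 3.43), Bcl11a with Tcf7 1.36 (0.689 to 2.68) and Bcl11a with Bcl11b 0.823 (0.374 to 1.81), against 0.656 in each, 0.816 and 0.698, and 0.293 and 0.343 in the 10x libraries. The labels name no animal for these cells, so they were pooled as a single sample.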

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

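Alternatives on recovered reads (edgeR, DESeq2), median-ratio scaling, leaving out the first library-number series, and removing cells by doublet score were chosen after seeing the data. Called genes are given as percent of the 24506 genes in the table, in the order Flt3- against Flt3+ ETP (0.339%, 83 genes), Bcl11b- DN2a against Flt3- ETP (1.96%, 481 genes), Bcl11b+ against Bcl11b- DN2a (1.38%, 338 genes) and Bcl11b- DN2a against total ETP (7.73%, 1895 genes). None of the 91 called results for genes named by the rule changed direction under any alternative fit of the bulk libraries. These results were selected as called in the main fit, and the largest rises and falls also for the same sign in every series. An unchanged direction was therefore largely fixed by the selection. Examples from the lists were not followed through all of these fits.

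Without the kit term the shares were 0.0408%, 0.143%, 0.0163% and 0.224%, and with NEBNext libraries only they were 0.0286%, 4.28%, 0.147% and 1.35%. With the library-number series as block they were 2.4%, 3.82%, 2.78% and 3.84%. The first share was 0.224% after quantile normalization and 0.208% with a pseudocount of 0.1. Fitting only the populations compared gave 2.34% in the first comparison and 0.575% in the third. Without the filter on low values the third was 0.792% and the fourth 3.26%. Leaving out each library in turn gave 0.0571% to 6.55%, 0.673% to 10.4%, 0.649% to 1.04% and 0.828% to 11.8%. The share of higher genes among those called crossed 50.0% in the first comparison (61.4%, but 20.6% without Flt3- ETP replicate 2), the second (40.7%, but 76.5% without that library) and the fourth (62.5%, but 39.4% without total ETP replicate 2). Of the named genes, 17 and 19 lost their call without Flt3+ ETP replicate 1 and 2, 24 without Flt3- ETP replicate 1 and 1 without its replicate 2, 11, 8 and 7 without Bcl11b- DN2a replicate 1, 2 and 3, 3, 4 and 9 without Bcl11b+ DN2a replicate 1, 2 and 3, and none without either total ETP library. A library left alone in its population was assumed to vary like the other populations.

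On recovered reads, DESeq2 gave 1.78%, 6.36%, 3.3% and 14.4%, and with the series as block 6.77%, 8.48% and 5.28% in the first 3. edgeR gave 2.99% in the second, and with the series as block 4.11%, 6.28%, 4.33% and 4.8%. Without the first series the first share was 0.171% and the second 1.14%. Other shares stayed within 1.5 times. Fits on fewer libraries have fewer degrees of freedom, and for the other alternatives the cause was not tested. Of 91 results for named genes, 74 lost their call without the kit term, 41 with NEBNext libraries only, 29 without the filter, 24 without the first series, 14 after quantile normalization, 10 with the compared populations only and 6 with a pseudocount of 0.1. Of the same results, 6 lost their call with edgeR and 1 with DESeq2, and none with limma with the series as block or with median-ratio scaling.

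The labels give replicate numbers within the NEBNext libraries, and runs of neighbouring library numbers, the series, group libraries further, but no label names an animal. With the number as block beside the kit, the shares were 1.11%, 3.4%, 2.37% and 15.7%. With population and kit removed, deviations were correlated between NEBNext libraries of different populations. The median correlation was 0.257 (0.051 to 0.823) in 9 pairs that share series and number and 0.243 in 4 that share the number only. It was -0.332 in 2 that share the series only and -0.426 in 10 that share neither. Removing population means forces deviations within a population to oppose each other, so part of this contrast follows from the fit.

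The ETP-like share was 11.7% at resolution 0.5, 9.65% without centring, 19.3% with at least 500 genes, 13.8% with doublets kept, where a DN2-like class was also named, and 9.09% with the 5% highest doublet scores removed. The unnamed share was then 77.9%, 79.6%, 69.8%, 71.9% and 80.1%. Committed-like and myeloid-like shares moved by less than the spread between libraries. Across all expressed genes, the correlation in library 2 turned to -0.013 for cluster 5 with Flt3+ ETP and to -0.074 for cluster 13 with Bcl11b+ DN2a. The cause was not tested. Many cells of the shallow committed-like cluster 8 fall under 4000 UMIs, and the effect of depth on co-detection was not compared between classes.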

Other observations

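The tests of the scaling of Flt3- ETP replicate 1, of RNA from mature thymocytes (with its condition on markers of other cells) and of other splits of the DN2a libraries were chosen after the result was seen.

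Interferon-induced, beta-globin and Cpa3 transcripts were high in some 10x clusters. Cluster 10, led by Ifit1, Isg15 and Rsad2, genes induced by interferon, held 3.15% of cells (mean of both libraries), and Isg15 reached 678 and 606 CPM there. Hbb-bt, a beta-globin gene, reached 1314 and 744 CPM in cluster 2 and 1606 and 889 CPM in cluster 3, against 6.51 and 7.24 CPM in the committed-like cluster 8. Cpa3 reached 402 and 406 CPM in cluster 1, beside Bcl11b and Il7r among its leading genes, so that transcripts usually assigned to erythroid or mast cells were found in clusters that lay near DN2a cells.

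Granule protein transcripts were higher in Flt3- ETPs. Had this come from scaling of Flt3- ETP replicate 1 alone, the pair made with SMART-Seq would have shown no rise. There the median log2 difference of the 18 myeloid genes was 1.46 relative to the median of all genes tested, with 16 above that median. Cells like those of the myeloid-like 10x cluster may have contributed. In all, 50 other leading genes of that cluster lay outside the lists and the called genes. Their median change was 0.27 relative to the median of all genes tested, which was -0.145, and 44 lay above that all-gene median. Leaving out called genes removed any cluster genes that passed in this same comparison, which can lower the median. The relative median of 0.27 lies between the bounds of 0.5 and 0.1, also relative, that were set for and against that source. For the myeloid genes a share of such cells and expression within ETPs therefore cannot be told apart. Elane was at 0.258 and 0.332 CPM outside the cluster, but most Mpo UMIs lay outside it. Cpa3 was at 261.9 and 334.7 CPM in the cluster and at 178.2 and 157.3 CPM outside. The cells outside include those near DN2a cells, such as cluster 1, where Cpa3 was among the leading genes. Bulk Flt3+ ETP had Cpa3 at 8.67 and 32.3 FPKM, so this comparison cannot settle the source of its rise of 2.67. Tcf7 (15.97 and 4.92 against 192.2 and 215.5 CPM) and Cd160 (3.19 and 9.84 against 28.8 and 25.9 CPM), which also rose, were lower in the cluster. This argues against such cells as the source of the Tcf7 and Cd160 rises, though the same outside cells were the reference.

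The median change of 24 G2/M genes was negative in Flt3- ETPs. If Flt3- ETP replicate 1 alone had caused this, the SMART-Seq pair would have shown no fall relative to the median of all genes tested. Relative to that median, the G2/M median was -0.64 in the SMART-Seq pair, with 0 of 24 genes above the all-gene median, and -0.47 in the other pair. The all-gene median itself was -0.029 in the SMART-Seq pair and -0.237 in the other, so the order of the 2 pairs depends on this centring. A difference in cycling between the populations stays open, since the call of this list was lost with an estimated correlation and no biological explanation was tested.

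Transcripts of T-cell genes, such as Cd3g at 46.2 FPKM against 0.998 in total ETP, were present in both ETP libraries of the first library-number series. Relative to the median of all 12112 genes tested, 5460 low genes outside the T-cell lists had a median log2 difference of -0.015. This argues against a large offset of low transcripts in that series. A smaller offset could be hidden, since the low genes are part of that reference. RNA of more mature thymocytes may have been present, as 7 markers of those cells had a median difference of 0.60 relative to the median of all genes, with 6 above it. Relative medians were also positive, without a test, for markers of stromal cells (1.06, 5 of 6 above the all-gene median) and dendritic cells (1.38, 7 of 9 above it). This keeps the source open, and the sort excluded lineage-positive cells. These marks were not confined to ETPs: Bcl11b- DN2a replicate 1 of the same series had Cd3g at 19.8 and Col1a1 at 8 FPKM, against Cd3g at 4.77 FPKM or less and Col1a1 at 0.014 FPKM or less in its other replicates. Bcl11b+ DN2a replicate 1 had Col1a1 at 5.345 FPKM, against 0.009 FPKM or less in its other replicates. Its Cd3g, at 51.1 FPKM, lay between theirs (90.6 and 34.5 FPKM). Col1a1 was thus raised in every library of that series, on both sides of the Bcl11b+ against Bcl11b- comparison.

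The 6 DN2a libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 338 called genes and the highest of the others gave 1.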
